A study of Mus musculus with 6 samples.

How the data were processed

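RNA was sequenced from the bone marrow of 6 C57/Bl6 mice aged 8 months, 3 with a knockout of nuclear myosin 1 (NM1 KO) and 3 wild type (NM1 WT). Nuclear myosin 1 is a form of the class I myosin encoded by Myo1c that carries extra residues at its start and is found in the nucleus. Per the labels' protocols, marrow was spun out of the cleaned femurs and tibiae of a single mouse for each sample. RNA was extracted with RNAzol, and libraries were made with a NEBNext Ultra II RNA kit and sequenced on an Illumina NextSeq. Each sample is therefore a separate mouse, and no cell type was sorted.

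The deposited files hold raw read counts per Ensembl gene, with no normalisation and no lines for unassigned reads. Per the submitters' processing notes, the tools were Trimmomatic 0.36, FastQC, HISAT2 2.0.4, SAMtools 0.1.19 and HTSeq, and the genome builds were GRCm38 and mm10. The annotation release, the strand setting and the counting options are not given in the sources used here. Without a stated strand setting, reads of overlapping or antisense genes cannot be told apart. Counts of near-identical paralogs, such as the Ear genes, are uncertain because reads shared between copies can be split or dropped. Low counts were nearly all even: in library NM1 KO 1, 2417 genes had a count of 2 and 6 genes a count of 1. Both mates of a read pair therefore appear to have been counted, which doubles the counts without adding information. An alternative with halved counts was run for this reason.

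Each file listed 46603 genes, of which 46091 matched a symbol and position in the GENCODE M21 annotation of GRCm38. Genes without a match held at most 0.0532% of a library. Library totals were 22618802, 21464506 and 21101616 counts in NM1 KO 1 to 3 and 15226446, 17580660 and 15145052 counts in NM1 WT 1 to 3. Normalised levels are given as CPM, counts scaled by library size, and after filtering and TMM scaling a level of 1 CPM stands for 14.7 to 23.0 counts. For a gene with 0 counts in a whole group, the floor was set at 6 counts over the group, equal to 3 read pairs. Floors cover counting error only, since the libraries hold no molecular identifiers.

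Genotypes were compared with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with genotype as the only term. Genes were kept by filterByExpr with its defaults, which left 15069 genes holding 99.9% of the counts, and libraries were scaled with TMM factors. Adjusted p is the Benjamini-Hochberg value over all tested genes, with a threshold of 0.05. Mean CPM values use the TMM factors and are given ± SD over 3 mice. Log2 fold changes are NM1 KO over NM1 WT, with their standard error (SE). Gene lists were tested with camera (limma 3.58.1), which compares the members of a list with all other tested genes, with a preset correlation of 0.01 between genes. It was run over 37 lists with at least 5 tested members, and p was adjusted over those lists. The class I myosins and the sex-linked genes served as checks and were left out, though they had 8 and 5 tested members. Camera was repeated with a correlation estimated for each list, and fry was run as a test of whether a list moves one way. Within each list, a count adjusted over the list alone is given beside the count over all genes. A list score is the mean log2 CPM of the members in a library.

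The groups, tests, gene lists and most alternatives were fixed before the data were examined. The genes named here follow a rule fixed at the same time. It takes Myo1c, and the 10 largest rises and 10 largest falls among protein-coding genes with a formal symbol that passed the threshold. These also had a mean of at least 1 CPM in the higher group and no overlap between the genotypes. For each list the rule takes up to 4 members past the threshold with the smallest p, or the 2 members of smallest p where fewer than 2 passed. It also takes the sex-linked genes Xist, Ddx3y, Uty, Kdm5d and Eif2s3y and the genes above 2% of any library. Any other gene named was chosen after its values were seen.

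Alternatives fixed in advance were RLE, upper-quartile and total-count scaling, other low-count filters, the likelihood ratio test, limma-voom with and without quality weights, and DESeq2 1.42.0. Others were a replicate block, each library left out in turn, other thresholds, and tests without haemoglobin, immunoglobulin and mitochondrial genes, without X and Y genes, or with protein-coding genes alone. Halved counts, counts thinned to the smallest total, the Y-linked state as a covariate, and tests without genes within 20 Mb of Myo1c were added after the data were seen. The pipeline was tested on simulated counts for 14828 genes with the means and library sizes of these samples. It recovered 58% of 100 genes changed 2-fold and 76% of 100 genes changed 4-fold, with 7 false calls among 141. A list raised 1.5-fold was found, and 0 of 36 other lists were called. The simulated genes were drawn independently, whereas list members in these data were correlated (estimated correlation 0.735 for platelet and megakaryocyte markers). The simulation therefore cannot show how often camera calls such lists falsely. It also held no difference between mice by Y-linked state and no library set apart from its group. Its 7 false calls thus give no rate of false gene calls for these data.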

Results

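Gene expression was measured by RNA sequencing in whole bone marrow of 3 NM1 KO and 3 NM1 WT mice, 1 library per mouse. The single comparison the design makes asks how loss of nuclear myosin 1 changes the marrow transcriptome, with platelets and the immune response as the theme of the study's title. Library totals lay between 15145052 and 22618802 counts, and every NM1 KO library was deeper than every NM1 WT library. Correlations of log2 CPM between libraries ranged from 0.937 to 0.973 across genes, which are not independent replicates, and no pair of libraries was identical. NM1 WT 2 stood apart: it correlated better with NM1 KO 1 (0.969) and NM1 KO 3 (0.962), though not NM1 KO 2 (0.956), than with NM1 WT 1 or NM1 WT 3 (0.957 each). On the second principal component (21.4% of the variance) it lay at -61.8, away from all other libraries (4.45 to 20.6). On the first principal component it lay at -4.39, between NM1 KO (-53.6 to -19.0) and the other NM1 WT libraries (53.4 and 44.1).

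Myo1c, the gene that encodes nuclear myosin 1 and the other Myo1c isoforms (ENSMUSG00000017774, chromosome 11, 75650504 to 75673910 on GRCm38), had 64.2 ± 8.28 CPM in NM1 KO and 102 ± 12.4 CPM in NM1 WT (SD, n = 3 each). Its values were 73.8, 59.1 and 59.7 CPM in the NM1 KO libraries and 89.8, 115 and 102 CPM in the NM1 WT libraries. All NM1 KO values lay below all NM1 WT values, but the log2 fold change of -0.67 (SE 0.14) did not pass the threshold in edgeR's quasi-likelihood test (adjusted p = 0.0516). Counts per gene add up all isoforms, so this level does not check the deletion of the nuclear form itself. Over the alternatives the adjusted p ranged from 0.00105 to 0.238 with the same direction. Of the 8 class I myosin genes, none passed, and Myo1f and Myo1g had log2 fold changes of -0.53 and -0.38.

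In NM1 KO marrow 20 of 28 platelet and megakaryocyte markers were higher, and 7 of 20 eosinophil, basophil and mast cell markers were lower. Ppbp, the platelet chemokine CXCL7, rose 3.99-fold, from 248 ± 67.9 to 990 ± 574 CPM (SD, n = 3), and Prg2, the eosinophil major basic protein, fell 3-fold, from 2043 ± 530 to 680 ± 173 CPM. Of 23 genes of marrow stroma 5 rose, among them Cxcl12, the niche chemokine, from 393 ± 64.8 to 1040 ± 332 CPM, and of 20 skeletal muscle genes 7 rose. All 4 lists passed camera with its preset correlation, and none passed with an estimated one (adjusted p = 0.14, 0.14, 0.203 and 0.14). In all, 117 of 15069 tested genes passed adjusted p under 0.05 in edgeR's quasi-likelihood test, 89 higher and 28 lower in NM1 KO. Of these, 101 changed at least 2-fold, 81 up and 20 down, and 112 were protein-coding. All 117 had values that did not overlap between genotypes, which largely follows from their selection by a small p in the same mice. Of all tested genes 20.5% did not overlap, against 10% given by chance. At an unadjusted p under 0.05 there were 2525 genes. The count moved with single libraries, and leaving a library out also changed the mix of Y-linked states described below. It was 40 without NM1 KO 2, 26 without NM1 WT 1, 30 without NM1 WT 3, 121 without NM1 KO 1, 177 without NM1 KO 3 and 344 without NM1 WT 2. It also moved with the test, from 37 genes with limma-voom to 786 with DESeq2. The excess of rises over falls was smaller with DESeq2 (403 up, 383 down), the likelihood ratio test (298, 243) and weighted limma-voom (255, 227) and turned without NM1 WT 2 (138, 206).

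Of 28 tested platelet and megakaryocyte markers, 20 rose in NM1 KO, 0 fell and 8 did not pass, with a median log2 fold change of 1.26. Adjusted over the list alone, 27 rose. Mpig6b, an inhibitory receptor of megakaryocytes and platelets, rose by 1.31 on the log2 scale (SE 0.17, adjusted p = 0.00743), from 20.3 ± 2.53 to 50.4 ± 8.65 CPM. Clec1b, the podoplanin receptor CLEC-2, rose by 1.52 (SE 0.20), Mmrn1, the carrier of factor V, by 1.77 (SE 0.24), and Tubb1, the platelet beta-tubulin, by 1.38 (SE 0.21). Others that passed were the glycoprotein Ib-IX-V genes Gp1ba, Gp1bb, Gp5 and Gp9, the integrin gene Itgb3, and Pf4, Thbs1 and Selp. The mean score of the list was 6.72 ± 0.442 in NM1 KO and 5.56 ± 0.148 in NM1 WT (log2 CPM, SD, n = 3), with no overlap. Camera gave an adjusted p of 1.08e-45, and adjusted p = 0.14 with an estimated correlation. The number of members that passed dropped to 9 without NM1 KO 2, 3 without NM1 WT 1 and 4 without NM1 WT 3. It was also 9 with the Y-linked state as a covariate and 8 with limma-voom, while 27 or 28 of the 28 members stayed positive in these fits.

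Of 30 tested cargo and secretion genes of platelet alpha and dense granules, 11 rose and 0 fell (14 up and 1 down adjusted over the list alone), with a median of 0.27. The 11 included Vwf, von Willebrand factor, which rose from 79.1 ± 6.87 to 180 ± 57.4 CPM, Pdgfb, a platelet growth factor chain, which rose by 1.31 on the log2 scale, and the secretory GTPase Rab27b. Of the 11, 7 also stood on the platelet marker list. The list passed with camera (adjusted p = 8.09e-09), with adjusted p = 0.14 with an estimated correlation, and its passing members dropped to 4 without NM1 KO 2, 1 without NM1 WT 1 and 1 without NM1 WT 3, and to 3 with limma-voom and 5 with the Y-linked state as a covariate. Of 45 tested genes of platelet activation signalling, 2 rose, Vwf and the laminin receptor subunit Itga6 (log2 fold change 0.99, SE 0.18), with a median of 0.17, and 7 rose and 1 fell adjusted over the list alone. Their camera adjusted p was 0.00432, with adjusted p = 0.504 with an estimated correlation and 0.0533 without NM1 WT 3.

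**Figure D1:**
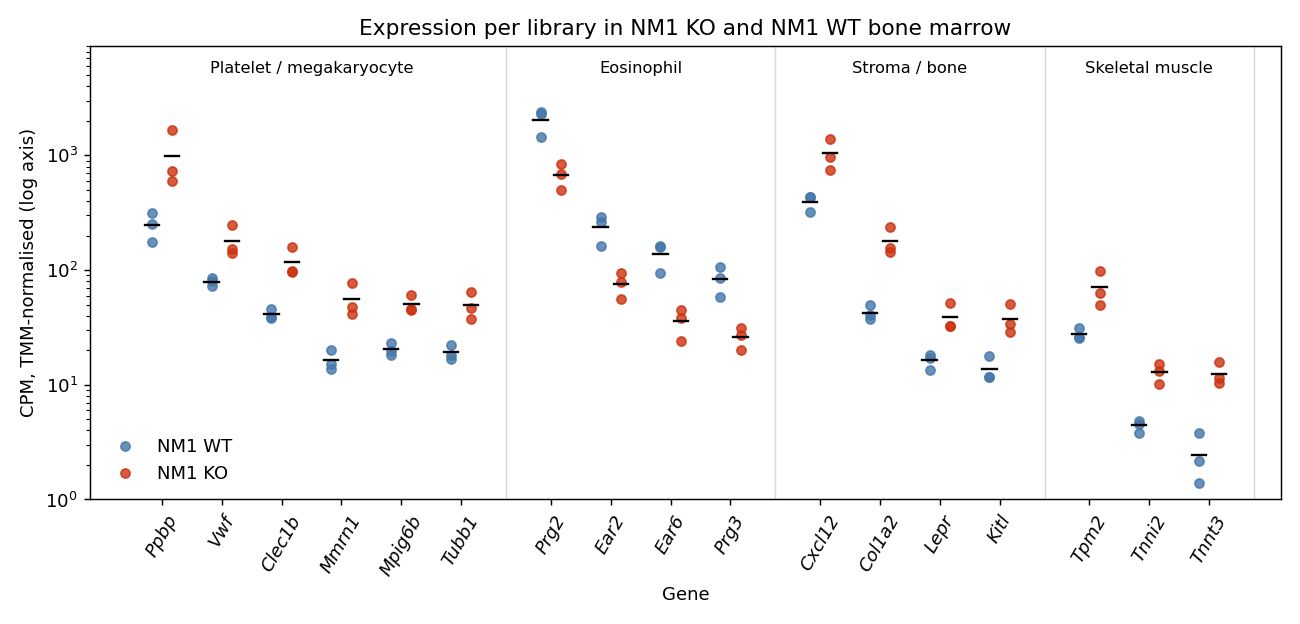
TMM-normalised CPM (log axis) of 17 genes in each NM1 WT (blue) and NM1 KO (red) library, with a black bar at the mean of 3 mice. Platelet, stroma and muscle genes such as Ppbp (990 against 248 CPM) and Cxcl12 (1040 against 393 CPM) lie higher in NM1 KO, and eosinophil genes such as Prg2 (680 against 2043 CPM) lie lower, with no overlap between genotypes.

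Of 20 tested eosinophil, basophil and mast cell markers, 0 rose and 7 fell in NM1 KO, with a median of -0.91, and 11 fell adjusted over the list alone. Prg2 had a log2 fold change of -1.59 (SE 0.22, adjusted p = 0.0107) and its neighbour Prg3, a homologous granule protein, -1.66 (SE 0.22). The eosinophil ribonuclease genes Ear6 and Ear2 had log2 fold changes of -1.95 (SE 0.25) and -1.64 (SE 0.23), though counts of these near-identical paralogs are uncertain. Epx, eosinophil peroxidase, fell from 205 ± 37.4 to 75.2 ± 24.0 CPM, and Prss34, a basophil protease, from 384 ± 64.0 to 193 ± 31.4 CPM. Camera gave adjusted p = 1.17e-17, and adjusted p = 0.14 with an estimated correlation. The number that fell was 4 without NM1 WT 3 and between 5 and 7 without any other single library.

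No neutrophil gene passed on its own. Both neutrophil lists were shifted down with the preset correlation, 8.80e-10 for granule genes and 7.57e-09 for mature markers, but each had adjusted p = 0.459 with an estimated correlation, and the scores of both overlapped between genotypes. Of 25 granule genes, 24 had a negative log2 fold change, with a median of -0.44, and 11 fell adjusted over the list alone. Lcn2, the iron-binding lipocalin, had 2642 ± 517 CPM in NM1 KO and 4353 ± 781 CPM in NM1 WT (adjusted p = 0.0879), and Pglyrp1, a peptidoglycan recognition protein, 732 ± 137 and 1251 ± 211 CPM (adjusted p = 0.0548). Of 22 mature neutrophil markers, 8 fell adjusted over the list alone, with a median of -0.43. Lrg1 and Ifitm6 had log2 fold changes of -0.95 and -0.74, both at adjusted p = 0.0513.

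Lists of the non-blood cells of the marrow cavity were shifted up with the preset correlation, though none passed with an estimated one and most of their members did not pass. Of 23 stromal and fibroblast genes, 5 rose and 0 fell (12 up adjusted over the list alone), with a median of 0.76. Cxcl12 rose by 1.40 on the log2 scale (SE 0.21), Kitl, stem cell factor, by 1.45 (SE 0.24), Lepr, the leptin receptor of niche stromal cells, by 1.26 (SE 0.21), and the proteoglycan gene Bgn by 1.03 (SE 0.19). Camera gave 3.09e-09, with adjusted p = 0.203 with an estimated correlation. The number that passed was 1 without NM1 KO 2, 3 without NM1 WT 2, 1 without NM1 WT 3 and 0 without NM1 WT 1, and 1 with limma-voom and 3 with the Y-linked state. Of 14 bone matrix genes, 1 rose, Col1a2, a chain of type I collagen, from 42.5 ± 5.93 to 179 ± 50.3 CPM (8 up adjusted over the list alone, median 0.92). Col1a1, the partner chain, had 207 ± 10.7 and 107 ± 39.1 CPM (adjusted p = 0.0786). The bone list gave 1.01e-08, with adjusted p = 0.14 with an estimated correlation.

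All 20 endothelial genes had a positive log2 fold change, with a median of 0.88. Of these, 2 rose, Vwf, which the 3 platelet lists also hold, and the junction protein gene Esam (1.17, SE 0.20), and 11 adjusted over the list alone, with a camera adjusted p of 2.17e-12 and adjusted p = 0.372 with an estimated correlation. Of 20 skeletal muscle genes, 7 rose from low levels and 0 fell, 12 up adjusted over the list alone, with a median of 1.34, which is the same with Mb at its floor. Tnnt3 and Tnni2, fast troponin subunits, reached 12.5 ± 2.82 and 12.9 ± 2.54 CPM from 2.46 ± 1.23 and 4.42 ± 0.554 CPM, and the tropomyosin gene Tpm2 reached 70.5 ± 25.6 from 27.5 ± 3.20 CPM. The muscle list had an adjusted p of 2.70e-13 and adjusted p = 0.14 with an estimated correlation, and 0 of its members passed without NM1 WT 1, 3 without NM1 KO 3, and 4 without NM1 KO 1, NM1 KO 2 or NM1 WT 3. With limma-voom 2 muscle genes passed. Whether muscle carried over with the marrow gave this rise was not tested.

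Of 13 adipocyte genes, 1 rose, Cfd, adipsin (complement factor D), and 5 rose and 1 fell adjusted over the list alone, with a median of 0.51. Fabp4, the fatty acid binding protein of fat and endothelium, had a log2 fold change of 1.35 (SE 0.30, adjusted p = 0.0565). The adipocyte list gave 2.43e-04, with adjusted p = 0.14 with an estimated correlation. Of 10 osteoclast genes, 1 rose, Itgb3, which the platelet list also holds, and Ctsk, cathepsin K, had 50.8 ± 45.4 and 12.0 ± 0.454 CPM (adjusted p = 0.0657). Adjusted over the list alone, 5 osteoclast genes rose and 2 fell, with a median of 0.59, a camera adjusted p of 0.024 and adjusted p = 0.459 with an estimated correlation, 0.0562 with the Y-linked state and 0.123 on voom values. The cartilage list had 4 tested members, too few for the list test, and none passed.

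None of 30 erythroid markers passed over all genes, while 13 rose adjusted over the list alone, with a median of 0.31. Camera gave the erythroid list 1.92e-06, with adjusted p = 0.469 with an estimated correlation. Car2, carbonic anhydrase 2, had 2724 ± 441 and 1756 ± 248 CPM (adjusted p = 0.0867) and Aqp1, aquaporin 1, a log2 fold change of 0.63 (adjusted p = 0.107). Hbb-bs and Hba-a1, the only genes above 2% of any library, had log2 fold changes of 0.30 and -0.26, neither past the threshold. Of 14 replication-dependent histone genes, 1 rose, Hist1h1c (0.87, SE 0.15), and 2 adjusted over the list alone, with a median of 0.65. Hist1h2bc had a log2 fold change of 0.57. The histone list gave 0.00408, with adjusted p = 0.469 with an estimated correlation, 0.0698 without NM1 KO 2 and 0.0831 without NM1 WT 2.

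Proliferation genes had a median of 0.13, with 0 of 38 past the threshold by either adjustment, over all genes or adjusted over the list alone. Mki67 had a log2 fold change of 0.46 and Ccne2 of 0.54. Their camera adjusted p was 0.00974, with adjusted p = 0.731 with an estimated correlation and 0.954 without NM1 KO 3. Of 19 early B cell genes, 0 passed and 1 rose adjusted over the list alone, with a median of 0.18, a camera adjusted p of 0.00478 and adjusted p = 0.459 with an estimated correlation. Rag1 and Rag2, the recombinase genes, had 43.7 ± 1.41 and 5.90 ± 0.246 CPM in NM1 KO against 20.7 ± 9.57 and 2.63 ± 0.737 CPM in NM1 WT (adjusted p = 0.083 and 0.134). Without NM1 KO 1 the early B cell list had an adjusted p of 0.0514. Of 20 stem and progenitor cell genes, Esam and Angpt1, angiopoietin 1 (1.38, SE 0.27), rose, and 4 rose adjusted over the list alone, but the list did not pass (adjusted p = 0.0821). It did pass without NM1 KO 1 (0.0442), NM1 KO 3 (0.0327) or NM1 WT 3 (0.0319) and with no low-count filter (0.0384).

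Among immune response lists, interferon-stimulated genes were shifted down with the preset correlation (2.80e-05), with a median of -0.44 over 41 genes, but had adjusted p = 0.49 with an estimated correlation. Their scores overlapped between genotypes, as NM1 WT 2 (4.48) lay within the NM1 KO range of 4.35 to 4.67, below NM1 WT 1 (5.16) and NM1 WT 3 (4.98). Adjusted over the list alone, 11 fell and 1 rose. Over all genes 1 passed, and it rose: Igtp, an immunity-related GTPase that lies on chromosome 11 and overlaps Irgm2 in the annotation, from 50.5 ± 10.9 to 138 ± 22.7 CPM. Oas2, an antiviral oligoadenylate synthetase, had 11.8 ± 1.08 and 25.7 ± 10.9 CPM (adjusted p = 0.0752). Of 22 genes of MHC class I presentation, 0 passed and 4 fell adjusted over the list alone, with a median of -0.24. Psmb8 and Tap2 had log2 fold changes of -0.47 and -0.56. The class I list gave 0.00408, with adjusted p = 0.49 with an estimated correlation and 0.0897 without NM1 WT 3. Of 13 MHC class II genes, 0 passed by either adjustment (adjusted over the list alone too). Lgmn and H2-DMb1 had log2 fold changes of 0.44 and -0.35, and the class II list did not pass (0.16), except without NM1 KO 1 (0.0370) or NM1 WT 1 (0.0125) and with the Y-linked state (0.0275).

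Of 23 complement genes, Cfd and Serping1, the C1 inhibitor (1.07, SE 0.20), rose, and 7 rose and 1 fell adjusted over the list alone, with a median of 0.36. Their camera adjusted p was 0.00209, with adjusted p = 0.14 with an estimated correlation. Of 29 monocyte and macrophage genes, Mrc1, the mannose receptor (1.46, SE 0.28), and Vcam1, an adhesion molecule also made by stroma (1.39, SE 0.26), rose, while 11 rose and 5 fell adjusted over the list alone, with a median of 0.04. This list gave 0.0268, with adjusted p = 0.588 with an estimated correlation, 0.222 without NM1 WT 1, 0.0653 without NM1 WT 3, 0.229 with the Y-linked state and 0.123 on voom values. Chemokine and cytokine receptors had a median of -0.13, with 0 of 33 past the threshold over all genes or adjusted over the list alone. Csf2rb and Csf2ra, subunits of the GM-CSF receptor, had log2 fold changes of -0.61 and -0.50. The receptor list gave 0.0419, with adjusted p = 0.525 with an estimated correlation, 0.0766 without NM1 KO 2, 0.176 without NM1 KO 3, 0.105 without NM1 WT 1 and 0.253 without NM1 WT 2.

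The T and NK, mature B, plasma and dendritic cell lists, cytokines and innate sensing genes did not pass camera. Of 32 T and NK cell genes, Cd4 rose from 12.4 ± 2.15 to 28.3 ± 5.55 CPM, and it was the only one adjusted over the list alone, while Nkg7 had a log2 fold change of -0.45 (list adjusted p = 0.695). Of 28 cytokines and chemokines, Cxcl12 rose, and 2 rose and 1 fell adjusted over the list alone. Il1a had 6.06 ± 3.95 and 1.45 ± 0.712 CPM, and the cytokine list had an adjusted p of 0.855, but 0.00373 without NM1 KO 3. No member of the following lists passed over all genes or adjusted over the list alone. Mature B cell genes, with Spib at 0.46 and Cd37 at -0.52, had a list adjusted p of 0.872. Plasma cell genes had 0.934, and 0.0353 without NM1 KO 1. Their immunoglobulin members varied between mice, with Ighg2b at 1127 ± 903 and 240 ± 150 CPM and Ighg1 at 110 ± 87.6 and 309 ± 155 CPM. Innate sensing and NF-kB genes, with Gsdmd at -0.51 and Nod2 at -0.72, had 0.113, but 0.0191 without NM1 KO 1, 0.0292 without NM1 WT 3 and 0.0166 with the Y-linked state. Dendritic cell genes, with Irf7 at -0.80 and Zbtb46 at 0.67, had 0.339.

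Among metabolic and nuclear lists, glycolysis genes had a median of -0.28, with 1 of 26 past the threshold. Camera gave the list 0.00408, with adjusted p = 0.469 with an estimated correlation and 0.0721 without NM1 WT 2. Hk2, hexokinase 2, was the 1 gene to fall, from 159 ± 37.3 to 70.6 ± 17.9 CPM, and 2 fell and 1 rose adjusted over the list alone. Gpi1, the next enzyme of the pathway, had 711 ± 101 and 1066 ± 99.4 CPM (adjusted p = 0.0848). None of 13 mitochondrially encoded genes passed, over all genes or adjusted over the list alone, with a median of -0.18 and mt-Co2 and mt-Nd6 at -0.69 and -0.42. Their list gave 0.0489, with adjusted p = 0.731 with an estimated correlation, 0.527 without NM1 KO 3, 0.191 without NM1 WT 1 and 0.0897 without NM1 WT 3. It also missed the threshold with upper-quartile factors (0.0513), library totals (0.0633), no X and Y genes (0.0512), the replicate block (0.0534) and thinned counts (0.0567).

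Nuclear genes of oxidative phosphorylation, with Ndufa1 at -0.37 and Cox4i1 at -0.29, had a list adjusted p of 0.181, and 0.0258 without NM1 KO 3. Genes of mTOR signalling, in which nuclear myosin 1 has been placed, had 0.395, with Pik3cd at -0.44 and Rps6kb1 at 0.38. RNA polymerase I and ribosome biogenesis genes, a process in which nuclear myosin 1 takes part, had 0.955, with Gnl3 at 0.35 and Taf1d at -0.32. Cytosolic ribosomal protein genes had 0.238, with a median of -0.06 and 14 of 38 positive, and the members of smallest p, Rps23 at 0.36 and Rpl5 at 0.44, went the other way. Immediate early and heat stress genes, with Atf3 at 7.03 ± 2.39 and 14.0 ± 2.97 CPM and Ier2 at -0.46 on the log2 scale, had 0.784, and 0.0258 in the opposite direction without NM1 KO 3. In these 5 lists 0 genes passed over all genes or adjusted over the list alone. Of 31 genes of the p53 response, 0 passed and 1 rose and 2 fell adjusted over the list alone, with Perp at -1.69 (adjusted p = 0.0516) and Chek1 at 0.74 (list adjusted p = 0.474).

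**Figure D2:**
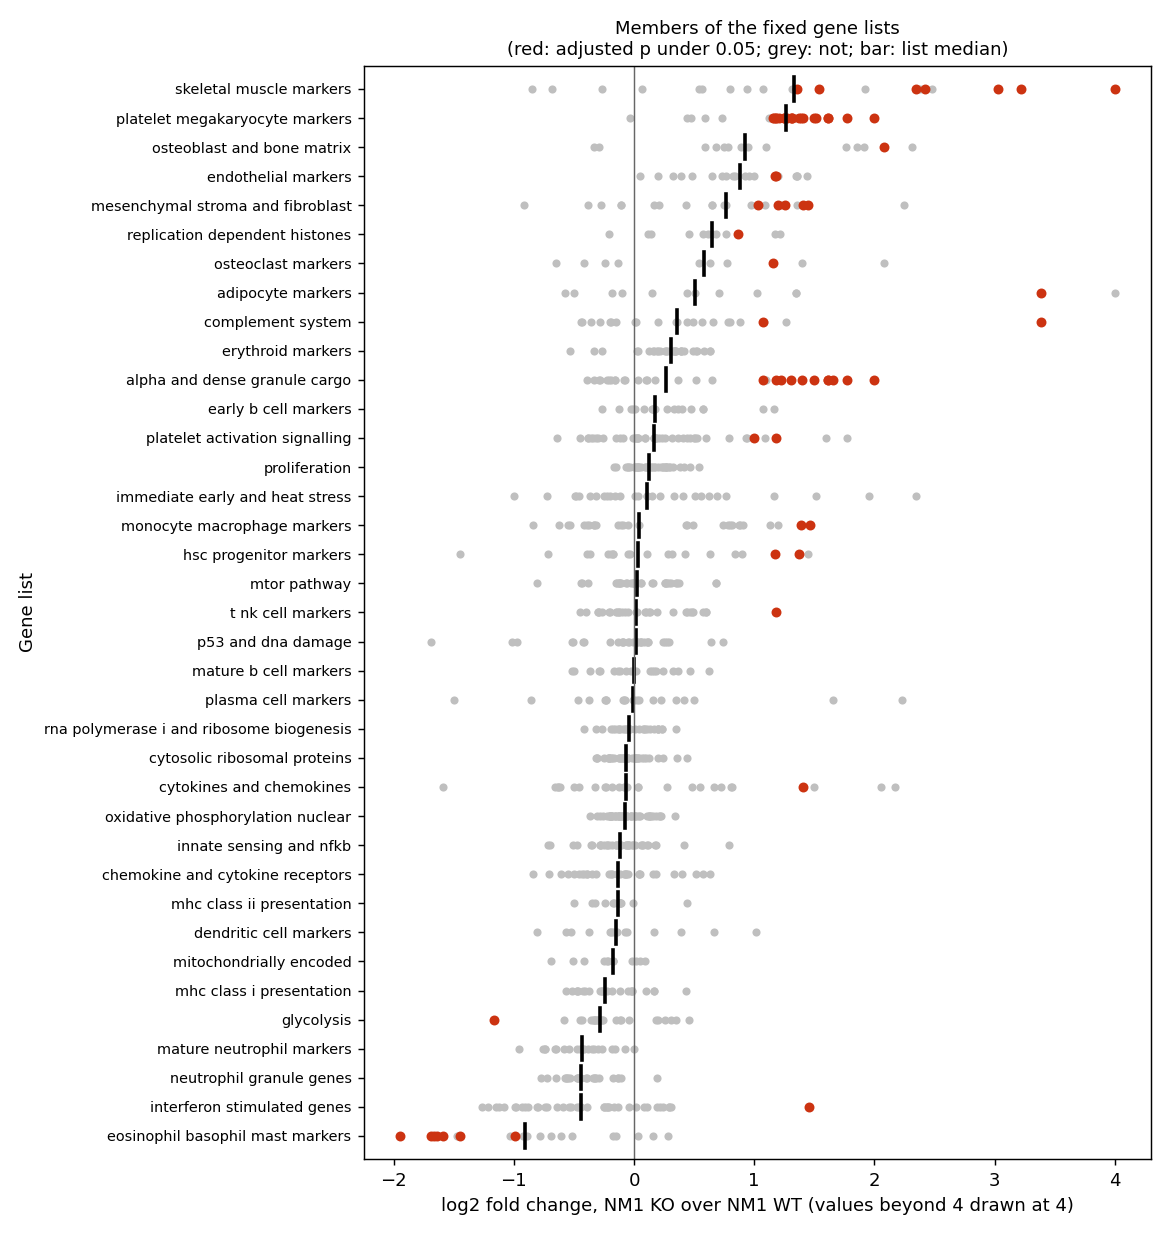
Log2 fold change (NM1 KO over NM1 WT) of every tested member of the 37 gene lists, ordered by the list median (black bar). Red points passed adjusted p under 0.05 and grey points did not, and values beyond 4 are drawn at 4. The platelet list has 20 red points to the right of 0 and the eosinophil, basophil and mast cell list has 7 to the left.

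In all, 23 of the 37 lists passed camera with the preset correlation, 15 up and 8 down. With a correlation estimated for each list 0 passed, 8 of them with an unadjusted p under 0.05, and 0 passed with fry. When the 6 mice were split into 3 and 3 so that genotypes mixed, camera with the preset correlation still called 9 to 22 lists. In such splits its adjusted p went down to 8.94e-17 for the platelet list and 4.20e-04 for the eosinophil, basophil and mast cell list. The sign of the median differed from that of the camera test in 6 lists and that of the mean in 2, none of which passed camera.

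The labels do not give the sex of the mice. Ddx3y, a Y-linked helicase gene, had 106, 92.0 and 80.5 CPM in NM1 KO 1, NM1 KO 2 and NM1 WT 2, and Xist, the RNA of the inactive X chromosome, at most 1.14 CPM there. In NM1 KO 3, NM1 WT 1 and NM1 WT 3, Xist had 272, 272 and 302 CPM and Ddx3y, Uty, Kdm5d and Eif2s3y had 0 counts. The genotypes thus held 2 and 1 libraries with Y-linked transcripts, and NM1 WT 2, which stood apart above, was the 1 in NM1 WT. The leave-one-out counts mostly went with this mix. Without NM1 WT 2 or NM1 KO 3, where the mix was less even, 344 and 177 genes changed. Without NM1 WT 1, NM1 WT 3 or NM1 KO 2, where it was more even, 26, 30 and 40 changed. Leaving out NM1 KO 1 also evened the mix, but 121 changed. Whether sex gave these shifts was not tested. With the Y-linked state as a covariate, 60 genes passed in place of 117, of which 54 were among the 117. Mitochondrial genes took 1.92 ± 0.319% of counts in NM1 KO and 1.98 ± 0.163% in NM1 WT, haemoglobin genes 7.38 ± 0.234% and 7.06 ± 1.38%, and immunoglobulin genes 0.891 ± 0.377% and 0.822 ± 0.172%.

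Among changed protein-coding genes with a formal symbol and at least 1 CPM in the higher group, the largest rises included muscle genes and genes of stromal or endothelial cells. Mb, myoglobin, had 0 counts in all NM1 WT libraries and 2.01 ± 0.579 CPM in NM1 KO, at least 15.8-fold higher than the floor of 6 counts over the group (adjusted p = 0.0212). Dkk1, a Wnt inhibitor, was likewise at least 8.53-fold higher (1.08 ± 0.412 CPM, adjusted p = 0.047). Myo15, an unconventional myosin of hair cells, rose by 3.66 on the log2 scale (SE 0.69), Car3, a carbonic anhydrase of muscle and fat, by 3.52 (SE 0.35), Nlrp1b, an inflammasome sensor, by 3.40 (SE 0.51), and Cfd by 3.39 (SE 0.50). Myl1, a fast muscle myosin light chain, rose by 3.22 (SE 0.58), Clec14a, an endothelial lectin, by 3.12 (SE 0.59), Pvalb, the muscle calcium buffer parvalbumin, by 3.03 (SE 0.61), and Cdh11, a mesenchymal cadherin, by 2.57 (SE 0.35). Some of these sizes rest on few counts in single NM1 WT libraries: over the alternatives Pvalb ranged from 2.59 to 4.35 and Nlrp1b from 2.98 to 4.39, each highest without NM1 WT 3, and Myo15 from 3.11 without NM1 WT 1 to 5.32 with weighted limma-voom.

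Among the same class of genes, the largest falls were Ereg, an EGF receptor ligand, and Ccdc92b. Ereg had a log2 fold change of -4.69 (SE 0.97), which rests on 2, 2 and 0 counts in NM1 KO against 22, 14 and 44 in NM1 WT. Ccdc92b (chromosome 11, 74619605 to 74641516) had 2.89 ± 0.291 CPM in NM1 KO and 30.0 ± 7.22 in NM1 WT, a log2 fold change of -3.37 (SE 0.23, adjusted p = 5.85e-05). It passed in every alternative in which it was tested. The lipoxygenase genes Alox12e and Alox15, which lie next to each other at 70315610 to 70322628 and 70344152 to 70352031 on chromosome 11, had log2 fold changes of -3.27 (SE 0.60) and -2.07 (SE 0.27). Alox12e rests on 6, 6 and 20 counts in NM1 KO, ranged from -4.12 without NM1 KO 3 to -2.97 without NM1 KO 1, and passed in 17 of 22 alternatives. Ear1, another eosinophil ribonuclease gene, had -1.69 (SE 0.30) and Fbln2, fibulin 2, -1.51 (SE 0.29), and Ear6, Prg3, Ear2 and Prg2 completed the 10.

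Several of these genes lie near Myo1c. Of 310 tested genes within 10 Mb of it, 8 changed, against 109 of 14720 others (odds ratio 3.55, 95% interval 1.48 to 7.34, Fisher's exact test p = 0.00292). Within 20 Mb, a width chosen after the positions were seen, 14 of 505 changed, 8 up and 6 down (odds ratio 3.99, Fisher's exact test p = 3.76e-05). They were Igtp, Irgm2, 2610507I01Rik, Myo15, Grap, Alox12, Alox12e, Alox15, Gp1ba, Nlrp1b, Ccdc92b, Gm26836, Slc6a4 and Epx. Fisher's test takes genes as independent, but Igtp and Irgm2 overlap in the annotation. Alox12, Alox12e, Alox15 and Gp1ba lie close together, between 70241457 and 70642036. The p-values may thus be too small and the interval too narrow.

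**Figure D3:**
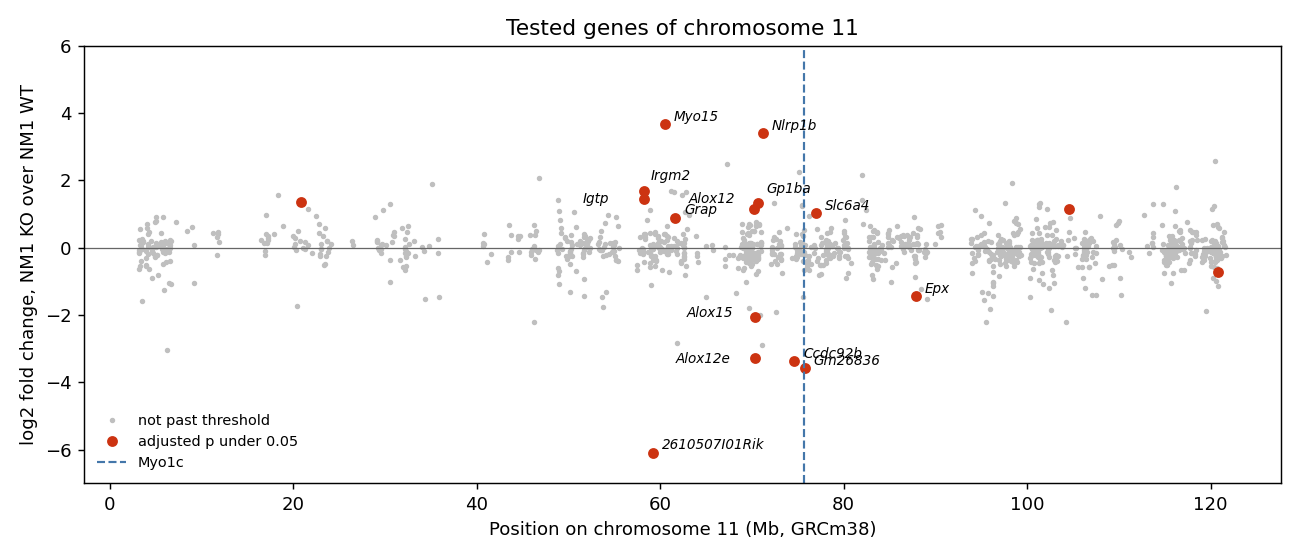
Log2 fold change (NM1 KO over NM1 WT) of each tested gene on chromosome 11 against its start on GRCm38 in Mb, with the position of Myo1c as a dashed line. Red points passed adjusted p under 0.05, and the 14 named ones lie within 20 Mb of Myo1c.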

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

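Halved counts, thinned counts, the Y-linked state as a covariate and the fit without genes within 20 Mb of Myo1c were chosen after the data were seen; the other alternatives were planned. All 117 changed genes kept their direction in every alternative in which they were tested, and no named gene reversed. The values of all 117 did not overlap between genotypes, so their sign could hardly turn, and the kept direction is no separate support. Of 46 named genes past the threshold, 22 missed it without NM1 KO 2, 30 without NM1 WT 1, 27 without NM1 WT 3, 24 with limma-voom and 16 with the Y-linked state. The count of changed genes (117, 89 up and 28 down) went to 1138 (621 up, 517 down) with no low-count filter, 541 (298, 243) with the likelihood ratio test, 786 (403, 383) with DESeq2, and 482 (255, 227) with weighted limma-voom. It was 37 (23, 14) with limma-voom, 357 (212, 145) at adjusted p under 0.1, 207 (135, 72) without haemoglobin, immunoglobulin and mitochondrial genes, 201 (134, 67) with protein-coding genes alone, and 60 (45, 15) with the Y-linked state. The falls alone moved to 50 without X and Y genes, 51 with halved counts and 18 without genes within 20 Mb of Myo1c. All changed genes in these fits came to 160, 159 and 95. With halved counts 108 genes rose, and 115 of the 117 were shared. Leaving out each library in turn gave 26 to 344 changed genes, 15 to 156 up and 10 to 206 down, and 24 (without NM1 WT 1) to 98 (without NM1 WT 2) of the 117 remained. The majority turned from rises to falls without NM1 WT 2 (138 up, 206 down). Fewer genes or mice enter some of these fits by construction. The leave-one-out counts rose where the mix of Y-linked states became less even. They fell where it became more even, except without NM1 KO 1. Beyond this the cause was not tested. RLE, upper-quartile and library-total scaling gave 114, 87 and 150 genes.

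The labels do not say what the replicate numbers mark, so the numbers were not taken to pair the samples. Same-numbered mice had correlated deviations of 0.0636, 0.115 and 0.0609, against -0.0784 to 0.0172 for unlike numbers. Each sample thus correlated best with its own number, and a pairing stays open. The replicate block gave 421 genes (229 up, 192 down; 116 of the 117 shared).

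The 23 lists that passed became 0 with an estimated correlation and 0 with fry, and stayed within 1.5 times of 23 otherwise. Reversals occurred only in lists that did not pass, and the cause was not tested. With other settings these were RNA polymerase I with upper-quartile factors (0.968) and protein-coding genes (0.855), immediate early genes with the block (0.513), cytokines with thinned counts (0.988), the Y-linked state (0.993) and voom values (0.961), and plasma cells with thinned counts (0.988). With a library left out, cytokines reversed without NM1 KO 1 (0.876) and NM1 KO 2 (0.961), T and NK cells without NM1 KO 1 (0.876) and NM1 WT 2 (0.823), and mature B cells without NM1 KO 1 (0.235) and NM1 WT 2 (0.557). Plasma cells reversed without NM1 KO 2 (0.857), NM1 KO 3 (0.253) and NM1 WT 2 (0.823), immediate early genes without NM1 KO 3, where they passed (0.0258), and NM1 WT 2 (0.549), and RNA polymerase I without NM1 KO 3 (0.593) and NM1 WT 1 (0.520). Without reversal, the other ends of the ranges over the libraries were 0.00373 for cytokines (without NM1 KO 3), 0.0353 for plasma cells (NM1 KO 1), 0.222 for T and NK cells (NM1 WT 3), and 0.651 for mature B cells and immediate early genes (NM1 WT 1 each). The simulated recovery of 2-fold changes (58%) was not split by expression level, so a limit set by depth was not measured.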

Other observations

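The genes described first, the search over symbol families, the use of the split by Y-linked state against sex, the 20 Mb window and the tests of the platelet pattern were chosen only after the results were seen. Of the 117 changed genes, 63 were on no list, 43 higher and 20 lower in NM1 KO. Gucy1b1, a subunit of the nitric oxide receptor, had 20.9 ± 10.6 CPM in NM1 KO and 6.19 ± 2.07 in NM1 WT (log2 fold change 1.75), Pde5a, which degrades cyclic GMP, 71.1 ± 30.7 and 29.8 ± 4.23 (1.25), and Mrvi1, a target of the cyclic GMP kinase, 41.8 ± 18.6 and 15.3 ± 1.67 (1.45). Prkar2b, a regulatory subunit of protein kinase A, rose by 0.77 on the log2 scale. Slc6a4, the serotonin transporter, rose by 1.03, Adra2a, an adrenergic receptor, by 2.01, Pros1, protein S, by 1.14 and its homologue Gas6 by 1.18. Adjusted p was under 0.05 for each in edgeR's quasi-likelihood test. These genes were picked by hand and stand for no tested group.

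Among the 20 lower genes, Il3ra, the interleukin 3 receptor, had 25.9 ± 2.63 CPM in NM1 KO and 64.0 ± 11.3 in NM1 WT, and Alox15, a lipoxygenase of eosinophils and macrophages, 19.7 ± 5.69 and 82.9 ± 27.4. Lgals1, galectin 1, had a log2 fold change of -0.84, Fasn, fatty acid synthase, -0.72, and Ifitm3, an antiviral membrane protein, -0.63. Gm8797 had the smallest p of all genes (log2 fold change 5.59, 98.1 ± 8.27 against 2.02 ± 0.307 CPM, adjusted p = 1.84e-08). A search over 235 families of gene symbols with at least 8 tested members found 0 past the threshold in camera with the preset or an estimated correlation; the smallest preset adjusted p was 0.211, shared by Klra, Col and Ifi genes.

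The count of 117 changed genes was set against chance, library totals and sex. Of the 10 splits of the 6 mice into 3 and 3, 1, the real one, gave as many genes, and the highest other was 16, for the split that follows the Y-linked state. For lists it was 1 of 10, with 23 in the real split and 9 to 22 in the others. The split with 22 (NM1 KO 1, NM1 KO 2 and NM1 WT 3 against the rest) had 0 genes past the threshold and a platelet list at camera adjusted p = 8.94e-17. The number of lists called with the preset correlation therefore hardly marks the real split. The mixed splits still follow genotype in part, and 10 splits are too few for a share under 0.05. Thinning every library to the smallest total left 129 genes, which argues against unequal totals. Every NM1 KO library was deeper than every NM1 WT library, so other differences that go with depth cannot be told apart from genotype. Sex as the whole source is argued against, since it would give the most genes in the split by Y-linked state, which gave 16 against 117 by genotype, and 60 genes passed for genotype with the state as a covariate. A part played by sex stays open, as the leave-one-out counts mostly followed the mix of Y-linked states. A drop of the count by more than 1.5 times in favour of the sex term was written before the result as what sex would do. The count dropped that far (117 to 60). Of 32 genes past the threshold on the Y-linked term, 0 were among the 117. This does not count against sex, since chance gives little overlap between such small sets of 15069 genes. The 117 were also selected for genotype. Direction within each state could not decide on sex either, since all 117 had values that did not overlap between genotypes. The median size of the log2 fold changes of the 117 went from 1.40 to 1.26 with the same median SE of 0.24. Residual degrees of freedom went from 4 to 3.

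The excess of changed genes near Myo1c was tested as DNA carried along with the targeted allele, which could differ from the wild type in sequence or regulation. The odds ratio was 3.55 within 10 Mb, where 2.58% of tested genes changed against 0.740% elsewhere, and 3.99 within 20 Mb (2.77% against 0.709%). Platelet, eosinophil or other cell-type genes that happen to lie there stay open as its source. Without any listed gene the odds ratio was 5.18 (6 of 286 genes, Fisher's exact test p = 0.00168), but this left out only Alox12 and Gp1ba of the changed genes within 10 Mb and kept Slc6a4, the serotonin transporter, and Alox15, which are on no list. Nlrp1b, Alox15, Ccdc92b, Igtp and Irgm2 may differ through linked DNA, while an effect of nuclear myosin 1 on its own chromosome is untested.

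The rise of platelet and megakaryocyte genes was set against the mix of tissue in the samples. As the source of the platelet rise, carried-over muscle is argued against. The summed rise of the muscle list was 0.0349 of that of the platelet list. Whether carried-over muscle raised the muscle genes themselves was not tested. A lower share of neutrophils would raise all other cell types alike, yet the platelet score rose above the T and NK cell score by 2.65 SD of the libraries and above the mature B cell score by 3.00 SD. More bone-lining tissue in the NM1 KO samples cannot be told apart from genotype, because the stroma score also rose, by 0.697 (log2, pooled SD 0.223), in the same mice. More megakaryocytes or platelets in NM1 KO marrow, or more transcript per cell, may each give this pattern, and cell counts would be needed to separate them.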
